A study of Mus musculus with 8 samples.

How the data were processed

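The series comprises 8 RNA-seq libraries of polyadenylated RNA, 4 from tumor and 4 from small intestine of Apc mutant mice, all labelled untreated. RNA was extracted with TRIzol, treated with DNase and column-purified, and libraries followed standard Illumina procedures, per the labels' protocols. Groups were taken from the tissue and source labels, and the titles give replicate numbers 1 to 4 in each group.

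The authors deposited a table of whole-number read counts per gene for all 8 libraries, which was used as deposited and carries no normalization. They also deposited a table of FPKM values per gene for the same libraries, that is, values scaled by the authors for library size and gene length. Per the submitters' processing notes, FastQC, STAR, Cufflinks 2.2.1, HTSeq 0.6.0 and the genome build GRCm38 were used. The role and parameters of each tool, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Counting per gene without a known rule for shared reads makes close paralogs (Defa, Cyp3a, Slc5a4, Bpifb, Ly6 and H2 genes) uncertain, and without a known strand setting reads of overlapping antisense genes cannot be told apart.

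The count table holds 43629 genes, of which 16347 have 0 counts in each library, and the FPKM table holds 43437 of them. Gene symbols were matched by Ensembl identifier for 42462 of the 43629 genes. Coordinates and gene types come from a GRCm38 annotation, matched by identifier. Library totals ran from 53856561 to 84433335 counts, so 3 counts correspond to 0.0331 to 0.0630 CPM. A gene with 0 counts in a group was given a floor of 3 counts per library, and a gene with 1 to 3 counts was given a ratio with a 95% exact binomial interval. Reads carry no molecular identifiers, so floors and intervals cover counting error only. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom of 38.9 or more over genes with at least 20 counts in the pair), so none was counted as a duplicate.

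Counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with TMM normalization, the filterByExpr filter and a design with tissue as the only term. P values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Standard errors were derived from the fold change and the F statistic. CPM values are TMM-scaled, and means are given ± SD over 4 libraries. FPKM values were tested with limma 3.58.1 (trend) on log2(FPKM + 1) for genes with a mean FPKM of at least 1, a scale that understates changes of low genes. Library measures were compared with exact 2-sided permutation tests.

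Gene lists, 31 in all, were fixed before the data were examined: pathways of sugar and fat metabolism, Wnt targets, cell cycle, hypoxia, inflammation, and markers of epithelial, stromal, neural, immune, adipose and pancreatic cells and of gut regions. Of 358 list symbols 357 were found in the table. Lists were tested with limma's camera at a preset correlation of 0.01, 2-sided, with adjustment over the lists, and camera with an estimated correlation and fry served as alternatives. Genes were named by a rule fixed at the same time. Named were Apc and each measured fructose gene, the 8 called protein-coding genes with the largest rise and the 8 with the largest fall at a mean of at least 10 CPM with groups that did not overlap, and Slc2a1, Hk1, Hk2, Fasn and Pkm in any case. From each other list, up to 3 called members with the largest change were named, plus the largest in the minority direction. Some genes that the rule names are not reported here. After the data were seen, it was counted how often each library was the highest or lowest of its group within a list, and its median ratio to the mean of the other libraries of its group was taken over the tested members. Further lists (pan-epithelial, hepatocyte, gastric, and a group of transcription factors and other genes) were chosen after the gene table was seen and appear only in the additional observations.

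The count test was tried on simulated counts drawn from the means and sizes of these libraries for the comparison of tumor with small intestine, over 16730 genes of which 200 were changed. It recovered 62% of genes changed 2-fold and 89% of those changed 4-fold, with 4.43% false calls among all calls. The limma test recovered 65% and 89%, with 5.52% false calls. Few genes were changed in the simulation, and evenly in both directions, whereas most genes were called in the real comparison. These rates therefore do not cover errors that come from the scaling between tissues.

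Alternatives were DESeq2's size factors, library totals without composition correction, normalization without the 50 most abundant genes, no low-count filter, a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, a minimum fold of 2, the replicate number as a block, and each library left out in turn. For FPKM they were a pseudocount of 0.1 and no filter on low values. One alternative was added after the data were seen: both small intestine libraries with B cell and adipocyte transcripts above the others were left out. Raw reads, alignments, alternative splicing and the mutant Apc allele were not analysed here.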

Results

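Polyadenylated RNA was sequenced from tumor and from small intestine of mice carrying a mutation in Apc, a tumor suppressor of the Wnt pathway whose loss predisposes the intestine to tumors. The series holds 4 tumor libraries and 4 small intestine libraries, all labelled untreated and of a mixed C57B6/129 background. Its title concerns high-fructose corn syrup, but no library here is labelled as having received it, so the comparison is between tissues. Gene-assigned read counts ran from 53856561 to 67371180 per library in tumor and from 62347648 to 84433335 in small intestine (exact 2-sided permutation p = 0.0857 for the totals). Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Xist, the transcript of the inactive X chromosome, was at or below 0.104 CPM (counts scaled to library total and TMM factor) in each library, and the Y-linked Ddx3y was at 34.6 CPM or higher in each.

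Tumor and small intestine differed across most of the transcriptome. In tumor, 22 of 22 Wnt target, 22 of 22 cell cycle, 13 of 15 fibroblast and matrix and 11 of 14 inflammatory genes rose. Of genes of absorptive enterocytes 18 of 18 fell, of fructose handling 9 of 9, of fatty acid oxidation 14 of 15 and of hormone-secreting cells 13 of 14. As whole lists these were called by limma's camera, but all except the Wnt targets lost the call with an estimated correlation (adjusted p of 0.056 to 0.45, against 0.046). Of 17029 genes tested, 12649 (74.3%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6619 higher and 6030 lower in tumor. A change of at least 2-fold was seen for 4758 of the higher and 3887 of the lower genes. The groups did not overlap in CPM for 11998 genes (70.5%), against the 2.86% that chance gives for 4 against 4. Principal component 1 held 87.8% of the variance and separated the tissues, and component 2 held 3.55%.

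The balance of higher and lower genes depended on the scaling between tissues. In small intestine the 50 most abundant genes took 22.1 ± 0.635% of counts, against 10.8 ± 0.442% in tumor (SD, n = 4 each; exact permutation p = 0.0286, Benjamini-Hochberg adjusted 0.0429 over 6 library measures). Trimmed-mean scaling (TMM), used for the values given here, adjusts for differences in composition on the assumption that most genes do not change. Its factors were 1.35 ± 0.0215 in tumor and 0.742 ± 0.0442 in small intestine. With 74.3% of genes called, that assumption was not checked, and the near-even balance of higher and lower genes rests on it. With library totals alone, 10564 genes were higher and 2996 lower in tumor, and the median of all genes moved up by 0.863 on the log2 scale. The deposited FPKM table, tested with limma on its own scale and filter, gave 8297 higher and 2326 lower of 10623 called. Of the genes called with TMM, 925 were called in the opposite direction without composition correction. Among members of the gene lists these were Tpi1 and Elovl6, named after their values were seen.

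**Figure D1:**
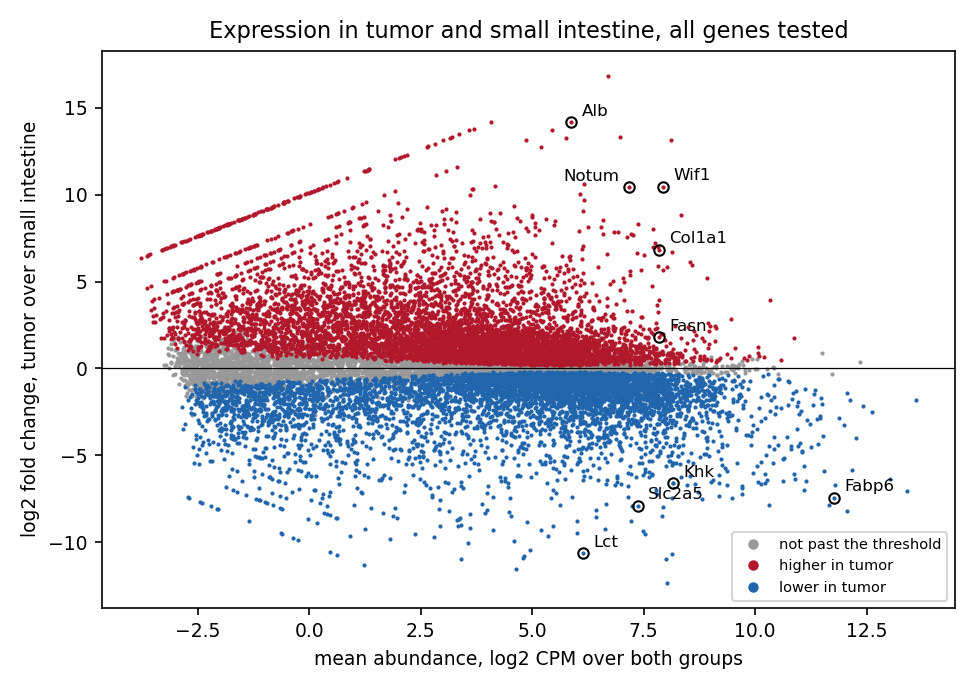
Log2 fold change of tumor over small intestine (vertical axis) against mean abundance in log2 CPM over both groups (horizontal axis) for the 17029 genes tested; points are genes, colored by whether they passed an adjusted p of 0.05. Of these, 6619 were higher and 6030 lower in tumor, and the diagonal lines at upper left are genes with few or no counts in small intestine, whose fitted fold change depends on the prior count.

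The fructose comparison concerns genes that carry fructose across the enterocyte membrane, convert it to triose phosphates or act around these steps. Sord, Glyctk and the transcription factor Mlxipl are of the last kind. All 9 measured members fell in tumor, with log2 fold changes from -9.24 to -3.13 (median -6.07), and all 9 fell under each other scaling too. Slc2a5, the fructose transporter of the brush border, stood at 1.39 ± 0.493 CPM in tumor and 328 ± 119 CPM in small intestine (SD, n = 4 each), a log2 fold change of -7.88 ± 0.39 (SE). Ketohexokinase, encoded by Khk, phosphorylates fructose and was at 5.83 ± 1.32 against 570 ± 110 CPM, a log2 fold change of -6.61 ± 0.24. The edgeR quasi-likelihood adjusted p was 2.31e-07 for Slc2a5 and 4.7e-08 for Khk. Triokinase (Tkfc) was at 30.4 ± 3.90 against 920.3 ± 148 CPM. The basolateral hexose transporter Slc2a2 showed a log2 fold change of -9.24, its relative Slc2a7 -8.73, the glycerate kinase Glyctk -3.13, the sorbitol dehydrogenase Sord -3.83 and the sugar-responsive transcription factor Mlxipl -3.97. The list as a whole had a camera adjusted p of 7.2e-11, and an adjusted p of 0.13 with an estimated correlation. Enterocyte genes had a median of -6.43.

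**Figure D2:**
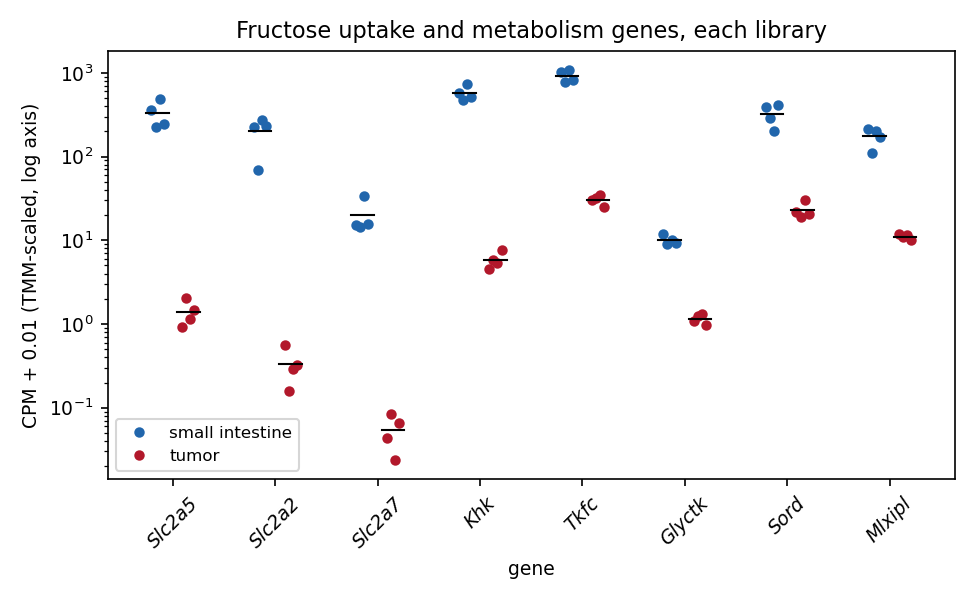
CPM plus 0.01 on a log axis (vertical) for 8 of the fructose genes (horizontal), with small intestine in blue and tumor in red; each point is a library and each bar the mean of 4. In each gene the 4 tumor libraries lie below the 4 small intestine libraries, with means of, for example, 1.39 against 328 CPM for Slc2a5 and 1.15 against 10.1 CPM for Glyctk.

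In genome build GRCm38, the counting features named here lie on chromosome 4 from 150119283 to 150144169 for Slc2a5 (ENSMUSG00000028976) and chromosome 5 from 30921431 to 30931248 for Khk (ENSMUSG00000029162). Each is annotated as protein-coding, and counts were summed per gene, so the Khk isoforms are not resolved. Apc (ENSMUSG00000005871, chromosome 18 from 34220924 to 34322552) was at 140 ± 5.90 CPM in tumor and 120.1 ± 24.2 CPM in small intestine (SD, n = 4 each). Its log2 fold change of 0.22 ± 0.14 did not pass the edgeR quasi-likelihood test (adjusted p = 0.188). Without composition correction it did, at 1.09 with an edgeR adjusted p of 4.76e-05, and the FPKM table gave 1.09 with a limma adjusted p of 4.32e-05; Apc was called under no other alternative, with an adjusted p of up to 0.407. Counts per gene do not separate the mutant from the normal Apc transcript.

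Of the 20 glycolysis and lactate genes, 12 rose, 4 fell and 4 did not pass the test; without composition correction 17 rose and 2 fell, and the triose phosphate isomerase Tpi1 turned from -0.38 to 0.49 on the log2 scale. The glucose transporter Slc2a1 was at 165 ± 32.6 CPM in tumor and 22.2 ± 4.46 CPM in small intestine, a log2 fold change of 2.89 ± 0.20 (SE). The hexokinases Hk1 and Hk2, which phosphorylate glucose, showed log2 fold changes of 1.59 ± 0.15 and 1.65 ± 0.41, and Hk2 stood at 2.23 without small intestine replicate 2. The lactate exporter Slc16a3 showed 1.85 ± 0.22, and the pyruvate kinase Pkm 0.66 ± 0.12. Pfkp, a phosphofructokinase, fell by 2.08 on the log2 scale. Gpi1 and the lactate dehydrogenase gene Ldha, both named after their values were seen, fell by 1.10 and 0.60. The change of Ldha lies within the shift between scalings. The list was not called (camera adjusted p = 0.071; 0.61 with an estimated correlation), although it was called without composition correction, with no low-count filter, without small intestine replicate 2 and by fry, which tests whether members move on balance one way (adjusted p from 0.00048 to 0.61 over all alternatives). In de novo lipogenesis, 8 of 12 genes rose and 3 fell; without composition correction 9 rose and 2 fell, the fatty acid elongase Elovl6 turning from -0.60 to 0.26. Fatty acid synthase, Fasn, was at 356 ± 26.2 against 102 ± 12.8 CPM, a log2 fold change of 1.81 ± 0.12. The desaturases Scd2 and Scd1 showed log2 fold changes of 2.85 ± 0.31 and 2.01 ± 0.52, while the mitochondrial acetyl-CoA carboxylase Acacb fell by 2.94. The lipogenesis list was not called (camera adjusted p = 0.18; 0.44 with an estimated correlation).

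Of 15 fatty acid oxidation and ketogenesis genes 14 fell, with a median log2 fold change of -2.13, and without composition correction 11 fell and 1 rose. Enterocyte markers had a lower median, -6.43, with 18 of 18 falling. The nuclear receptor Ppara, which drives these genes, was at 0.752 ± 0.180 CPM in tumor and 22.6 ± 7.97 CPM in small intestine. The peroxisomal enzyme Ehhadh fell by 3.67 on the log2 scale, and the thiolase Acaa1b by 6.94 (-6.25 without small intestine replicate 4). Gluconeogenesis genes (median -3.42) fell in 6 of 7 cases, led by G6pc, Pck1 and Fbp1, and without composition correction 5 fell and 1 rose. G6pc, which releases free glucose from its phosphate, was at 0.0430 ± 0.0300 CPM in tumor and 62.1 ± 54.8 CPM in small intestine, a log2 fold change of -10.46 (-9.65 without small intestine replicate 3). Pck1 was at 1.96 ± 0.438 against 488 ± 389 CPM and Fbp1 at 0.693 ± 0.186 against 88.0 ± 33.8 CPM. The camera adjusted p was 1.7e-07 for fatty acid oxidation and 0.00034 for gluconeogenesis, and the adjusted p with an estimated correlation was 0.29 and 0.22. In the pentose phosphate pathway, Taldo1 and Tkt fell by 1.18 and 1.13 on the log2 scale and the other 5 of 7 genes did not pass the test, but those 5 rose without composition correction (camera adjusted p = 0.44; 0.7 with an estimated correlation). Among hypoxia targets 4 of 11 rose (Slc2a1, P4ha1, Bnip3 and Egln3, the last named after its value was seen) and 1 fell, Ndrg1, at -1.16. Without composition correction 9 rose and none fell, Ndrg1 standing at -0.30 with an edgeR adjusted p of 0.0884 and at -0.22 with a limma adjusted p of 0.168 in the FPKM table, and below 0.05 under every other alternative; the hypoxia list was not called (camera adjusted p = 0.34; 0.62 with an estimated correlation).

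Wnt target genes rose without exception. All 22 measured members rose under each scaling, and with TMM their log2 fold changes were 1.56 or more with a median of 3.90. Notum, a secreted enzyme that inactivates Wnt proteins, was at 290.1 ± 20.5 CPM in tumor and 0.208 ± 0.178 CPM in small intestine, a log2 fold change of 10.43 ± 0.53 (11.09 without small intestine replicate 1). The secreted Wnt inhibitor Wif1 was at 488 ± 35.8 against 0.341 ± 0.162 CPM. Dkk2, another secreted Wnt modulator, held 24407 counts over the 4 tumor libraries and 2 over the 4 small intestine libraries, a ratio of 8090 (95% exact binomial interval 2240 to 66800). The list had a camera adjusted p of 2e-18 and was the only list called with an estimated correlation (adjusted p = 0.046). Intestinal stem cell markers rose in 9 of 12 cases, among them Slc14a1, Lgr5 and Msi1. Lgr5, a receptor that marks crypt base stem cells, was at 45.9 ± 12.7 against 3.93 ± 1.87 CPM. Olfm4, another stem cell marker, was at 24.6 CPM in tumor and 34.2 CPM in small intestine and did not pass the edgeR test (adjusted p = 0.534); it was named after its value was seen. The stem cell list had a camera adjusted p of 0.014 (0.2 with an estimated correlation).

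Fetal-like epithelium markers, which mark regenerating and embryonic gut, rose in 12 of 12 cases with a median log2 fold change of 4.19. These libraries do not show which cells held the transcripts, and most fibroblast, endothelial and macrophage genes rose too. A fetal-like state of the epithelium was therefore not tested. Spp1, a secreted phosphoprotein, was at 66.8 ± 20.4 CPM in tumor and 0.331 ± 0.301 CPM in small intestine. Anxa8 showed a log2 fold change of 7.92, and 9.22 without small intestine replicate 4. Cell cycle genes rose in 22 of 22 cases, with a narrower spread of log2 fold changes from 0.69 to 2.74. Tumor replicate 4 was the highest tumor library in 20 of 22, and replicate 3 the lowest in 18. Small intestine replicate 3 was the highest of its group in 16, at a median ratio of 1.44 to the mean of the others, and replicate 4 the lowest in 14. The topoisomerase Top2a was at 369 ± 41.9 against 73.4 ± 22.1 CPM, with Bub1 and Ccnb1 at log2 fold changes of 2.74 and 2.49. Both lists rose in full under each scaling. The camera adjusted p was 1.3e-05 for the fetal-like list and 1.1e-06 for the cell cycle, and the adjusted p with an estimated correlation was 0.13 and 0.45.

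Most markers of enterocytes, enteroendocrine cells and goblet cells fell. All 18 enterocyte markers fell under each scaling, with log2 fold changes from -10.62 to -3.19 and a median of -6.43 with TMM, and a median of -5.57 without composition correction. Lactase, Lct, was at 0.0851 ± 0.0304 CPM in tumor and 140.2 ± 129 CPM in small intestine, a log2 fold change of -10.62 (-9.75 without small intestine replicate 3). Trehalase, Treh, was at 0.684 ± 0.332 against 298 ± 44.2 CPM and the lipoprotein component Apoc3 at 0.463 ± 0.253 against 173 ± 75.6 CPM. Enteroendocrine markers fell in 13 of 14 cases (12 without composition correction), with the incretin Gip at 0.0215 ± 0.00723 against 23.7 ± 10.1 CPM. Neurod1 and Sst fell by 6.89 and 6.48, Sst standing at -7.38 without tumor replicate 3. Tumor replicate 4 was the lowest tumor library in 13 of 14 enteroendocrine markers, at a median ratio of 0.36 to the mean of the other tumor libraries. Goblet cell markers fell in 7 of 10 cases, Zg16 being at 100.3 ± 36.8 against 5882 ± 1261 CPM, with Guca2a at a log2 fold change of -4.49. Clca1, a product of goblet cells, fell by 4.45 (-5.44 without tumor replicate 3). Tumor replicate 4 was the lowest tumor library in 10 of 10 goblet markers, at a median ratio of 0.298, with the mucin Muc2 at 207 CPM against 645 to 978 CPM in the other tumor libraries and Tff3 at 63.9 against 185 to 223 CPM (both chosen after their values were seen). Without that library 8 of 10 fell. Camera adjusted p values were 3.5e-20, 6.5e-07 and 0.0039 for enterocyte, enteroendocrine and goblet markers, and the adjusted p with an estimated correlation was 0.056, 0.2 and 0.52.

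Paneth cell markers went both ways, with 3 of 10 rising and 6 falling. In 10 of 10 small intestine replicate 1 was the highest small intestine library, at a median ratio of 2.59 to the mean of the others, with the lysozyme Lyz1, chosen after its values were seen, at 6617 CPM against 1840 to 2099 CPM. Tumor replicate 4 was the lowest tumor library in 9 of 10, at a median ratio of 0.415. Without small intestine replicate 1, and likewise without tumor replicate 4, 3 rose and 6 fell. The antimicrobial peptide gene Defa22 was at 30.1 ± 5.77 CPM in tumor and 640.1 ± 411 CPM in small intestine. Pla2g2a, the gene of a secreted phospholipase, is annotated as a polymorphic pseudogene, so its counts do not tell whether a working enzyme was made. It was at 433 ± 38.1 against 28.3 ± 17.1 CPM, and the protease gene Habp2 showed a log2 fold change of 3.51 (4.25 without small intestine replicate 1). Defa genes are near-identical copies, so their counts are uncertain one by one. Tuft cell markers also split, with 7 of 11 falling and 2 rising. Trpm5, a cation channel of tuft cells, fell by 3.16 on the log2 scale, whereas the actin-binding Avil rose by 3.95. Tumor replicate 3 was the highest tumor library in 9 of 11, at a median ratio of 2.05 to the mean of the others. Gfi1b showed a log2 fold change of -2.75 at under 1 CPM in both tissues (-4.39 without tumor replicate 3), and was not called without composition correction (-1.92, edgeR adjusted p = 0.0533, with 0.000142 to 0.0649 over all alternatives). Without composition correction 5 Paneth and 5 tuft markers fell, and 3 and 2 rose. Neither list was called (camera adjusted p = 0.56 and 0.44; 0.86 and 0.79 with an estimated correlation).

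All 8 distal small intestine genes fell under each scaling, with a median of -6.10 with TMM beside -6.43 for the enterocyte markers. Among them was the ileal bile acid binding protein Fabp6, at 40.0 ± 17.4 CPM in tumor and 6922 ± 1781 CPM in small intestine. Cubn and Amn, partners in vitamin uptake by the ileum, fell by 7.20 and 6.97 on the log2 scale (list camera adjusted p = 1.8e-08; 0.2 with an estimated correlation). Of 8 proximal genes, 3 rose and 4 fell. The transcription factor Onecut2 was at 141 ± 34.1 against 0.257 ± 0.228 CPM, a log2 fold change of 9.07 (9.78 without small intestine replicate 2). The growth factor Fgf10 held 889 counts in tumor and 3 in small intestine, a ratio of 196 (95% exact binomial interval 67 to 954). The proximal list's median (-1.10) and mean (-0.12) were negative while camera's direction was up, at an adjusted p of 0.95; without composition correction camera's direction was down and 4 rose and 3 fell. Of 4 colon genes tested, 2 rose (Aqp8 and B3galt5) and 2 fell, among them Sult1c2 (B3galt5 named after its value was seen), Aqp8 at a log2 fold change of 6.63 and at 8.25 without small intestine replicate 4. The colon list had a median of -0.15 and a mean of 0.87 with camera's direction down (adjusted p = 0.52; 0.63 with an estimated correlation), and its median was 0.71 without composition correction. Without any 1 tumor library, or without small intestine replicate 3, a further gene passed the low-count filter and the median over 5 genes lay between -2.795 and -2.625.

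Most fibroblast, matrix and endothelial genes rose in tumor. Fibroblast and matrix genes rose in 13 of 15 cases with a median log2 fold change of 4.50, and without composition correction 14 rose. Collagen gene Col1a1 was at 455 ± 108 CPM in tumor and 3.99 ± 2.37 CPM in small intestine, and fibronectin, Fn1, at 427 ± 106 against 2.85 ± 0.858 CPM. Timp1, an inhibitor of matrix proteases, showed a log2 fold change of 7.24, while Fap, at 1.74 CPM or less in both tissues, fell by 2.12. All 9 endothelial markers rose under each scaling, with Cdh5 at 96.8 ± 18.4 against 1.65 ± 1.42 CPM, a log2 fold change of 5.86 (6.45 without small intestine replicate 1), and Vwf and Emcn at 4.73 and 4.25. The camera adjusted p was 1.1e-06 and 0.00059, and the adjusted p with an estimated correlation was 0.22 and 0.29. Smooth muscle markers moved less, with a median of 0.89. Acta2, smooth muscle actin, was at 66.5 ± 5.55 against 12.6 ± 6.25 CPM and Actg2 at 20.5 ± 2.94 against 5.75 ± 4.23 CPM, whereas Mylk fell by 2.14. Among small intestine libraries replicate 3 was the highest in 10 of 10 and replicate 2 the lowest in 9. In that list 5 of 10 rose and 1 fell, and without composition correction 9 rose and 1 fell (camera adjusted p = 0.5; 0.83 with an estimated correlation). Of 5 neuron and glia markers tested 3 rose, among them Uchl1 and Ret, by 3.25 and 1.52 (camera adjusted p = 0.44; 0.61 with an estimated correlation). Ret was not called without both small intestine replicates 1 and 2, at 1.39 with an edgeR adjusted p of 0.0811, the highest over its alternatives, which began at 0.000604.

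Neutrophil markers rose in 9 of 9 cases (6 in the FPKM table), from low levels, Trem1 being at 4.66 ± 2.31 CPM in tumor and 0.0661 ± 0.0420 CPM in small intestine. Ly6g and Mmp8 showed log2 fold changes of 6.39 and 5.98, and 8.96 and 9.77 without small intestine replicate 2. Tumor replicate 1 was the highest tumor library in 8 of 9, at a median ratio of 3.01 to the mean of the others. Small intestine replicate 2 was the highest of its group in 7 of 9, at a median ratio of 21.5. The list's median log2 fold change was 5.173 with all libraries and 7.635 without small intestine replicate 2. Macrophage markers rose in 10 of 11 cases, Cd14 at 71.7 ± 31.8 against 12.1 ± 3.56 CPM, with Fcgr1 and Adgre1 at log2 fold changes of 2.57 and 2.52. Inflammatory mediators rose in 11 of 14 cases under each scaling. Tumor replicate 4 was the lowest tumor library in 10 of 14, at a median ratio of 0.421 to the mean of the others. Tumor replicate 1 was the highest in 9 (1.51), and small intestine replicate 2 the highest of its group in 8 (1.63). The neutrophil chemokine Cxcl5 was at 36.0 ± 23.9 against 0.0219 ± 0.0262 CPM, a log2 fold change of 10.52 (11.31 without small intestine replicate 1), and Cxcl1 showed 8.23 (9.07 without small intestine replicate 2). Lcn2, an iron-scavenging protein of inflamed epithelium, was at 330 ± 83.2 against 1.05 ± 0.850 CPM, while the nitric oxide synthase Nos2 fell by 2.27. The camera adjusted p was 0.037, 0.043 and 0.0013 for neutrophil, macrophage and inflammatory lists, and the adjusted p with an estimated correlation was 0.6, 0.59 and 0.45. Without small intestine replicate 3 neither the neutrophil nor the macrophage list was called (limma's camera adjusted p = 0.0507 and 0.0774), and without tumor replicate 4 the macrophage list was not (0.0507). Both calls were also lost without composition correction (0.262 and 0.0966), on FPKM (0.252 and 0.115) and at a mean of at least 1 CPM (0.0529 and 0.0585), and the macrophage call with DESeq2 (0.0529). The inflammatory list lost its call on FPKM (0.0668). Over all alternatives these p values ran from 0.00057 to 0.6 for the neutrophil list and from 0.00048 to 0.59 for the macrophage list.

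Most T cell markers, part of the B and plasma cell markers and all MHC class II genes fell. T cell markers fell in 11 of 12 cases, and in 6 without composition correction. The granzyme gene Gzma was at 12.2 ± 5.99 CPM in tumor and 192 ± 136 CPM in small intestine, and Cd3e and Cd3g, parts of the T cell receptor complex, fell by 3.61 and 3.40 on the log2 scale. The T cell list was not called (camera adjusted p = 0.056; 0.63 with an estimated correlation), but was called without tumor replicate 4 (0.041) and without small intestine replicate 1 (0.0417) or 4 (0.0095). It was also called without composition correction (0.00519), with no low-count filter (0.00869), on FPKM (0.000309) and by fry (0.00961), with a range over all alternatives of 0.000309 to 0.628. Small intestine replicate 2 was the highest small intestine library in 12 of 12 T cell markers, at a median ratio of 2.37 to the mean of the others, and replicate 4 the lowest in 11. B and plasma cell markers fell in 5 of 9 cases, and small intestine replicates 2 and 4 were the highest and the lowest of their group in 8 each, as tumor replicate 1 was the lowest of its group in 8. Immunoglobulin heavy and light chain genes, transcribed by B and plasma cells, took 0.939 ± 0.499% of counts in tumor and 0.297 ± 0.175% in small intestine, a difference that did not pass the test (SD, n = 4 each; exact permutation p = 0.0857, adjusted 0.0857). Ms4a1, a surface protein of B cells, was at 0.131 ± 0.0298 CPM in tumor, against 29.3 ± 20.03 CPM in small intestine, and Cd79b fell by 3.96. Ms4a1 reached 36.3 and 54.5 CPM in small intestine replicates 1 and 2, and 13.98 and 12.4 CPM in replicates 3 and 4. The plasma cell joining chain Jchain, named after its value was seen, was at 536 CPM in tumor and 391 CPM in small intestine (edgeR adjusted p = 0.496), and the list was not called (camera adjusted p = 0.16; 0.68 with an estimated correlation). It was called without composition correction (0.022), on FPKM (0.0192) and by fry (0.0181). All 7 MHC class II genes fell under each scaling, with log2 fold changes from -3.66 to -2.29 with TMM (median -2.75, and -1.90 without composition correction). Tumor replicate 4 was the highest tumor library and small intestine replicate 2 the highest small intestine library in 7 of 7, and small intestine replicate 4 was the lowest in 7 of 7. H2-Aa was at 144 ± 46.9 against 1819 ± 878 CPM, with H2-Ab1 and H2-DMa at log2 fold changes of -3.24 and -3.15 (list camera adjusted p = 0.012; 0.57 with an estimated correlation).

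Among markers of neighboring tissues, Cela1 was the 1 pancreatic acinar gene of 11 expressed enough to test, and it rose by 3.05 on the log2 scale (list camera adjusted p = 0.098; 0.29 with an estimated correlation). Of 7 adipocyte genes, Cidec fell by 3.74 and Lpl did not pass the test (list camera adjusted p = 0.44; 0.61 with an estimated correlation). The adipocyte genes Adipoq and Cfd were at 2.78 and 12.4 CPM in small intestine replicate 1, at 1.49 and 4.49 CPM in replicate 2, and at or below 0.293 CPM in the other small intestine libraries, with 0 counts in each tumor library. Cidec ran the other way, at 57.11, 47.91, 78.65 and 125.9 CPM in small intestine replicates 1 to 4. The fall of Cidec is therefore no measure of fat tissue here. Mitochondrial genes took 3.40 ± 1.55% of counts in small intestine (5.59% in replicate 1) and 1.58 ± 0.186% in tumor (exact permutation p = 0.0286, adjusted 0.0429).

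**Figure D3:**
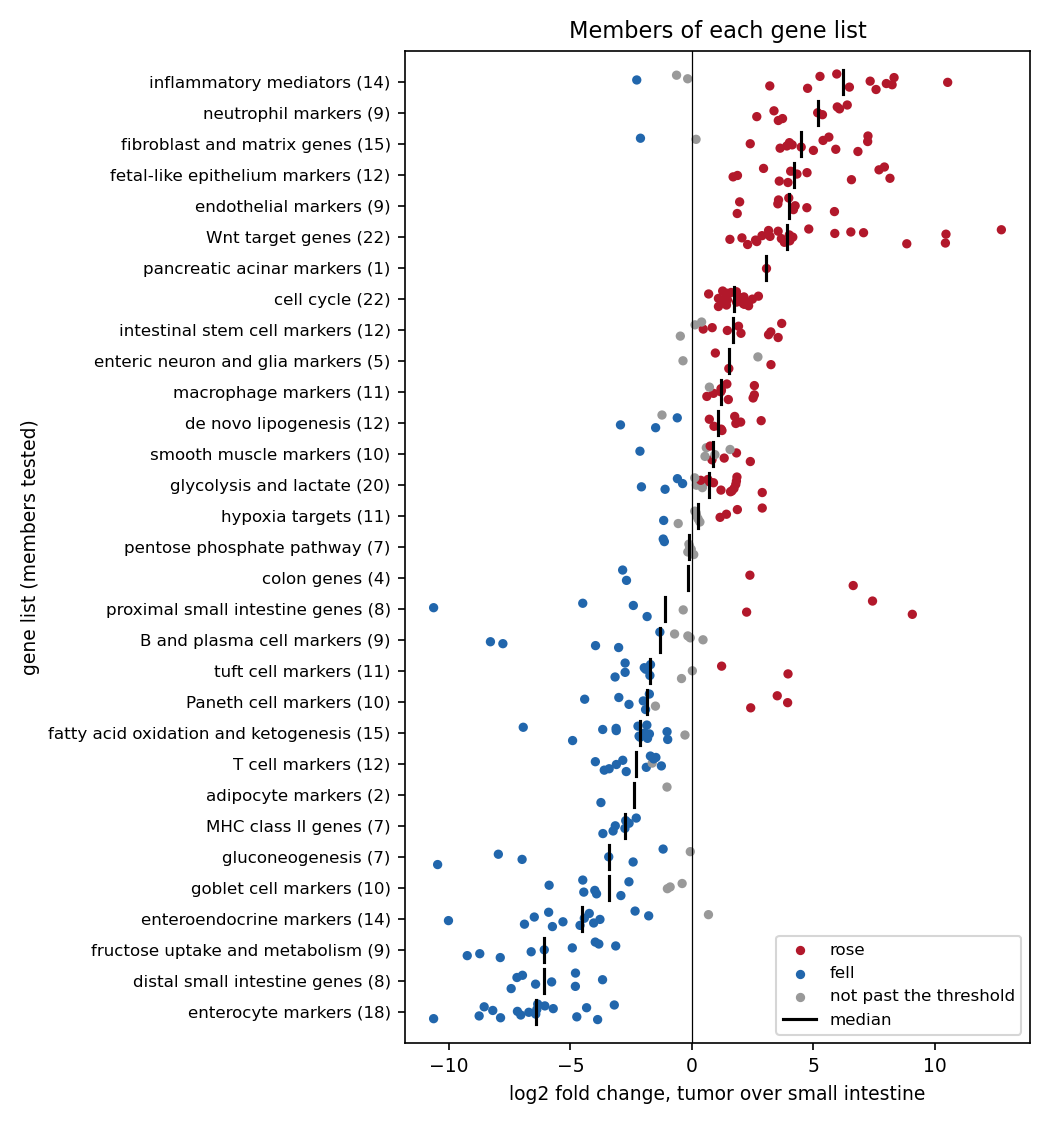
Log2 fold change of tumor over small intestine (horizontal axis) for each tested member of the 31 gene lists (vertical axis, number tested in brackets); points are genes, colored by whether they rose, fell or did not pass an adjusted p of 0.05, and black bars are list medians. Enterocyte (-6.43), distal small intestine (-6.10) and fructose (-6.07) lists lie lowest and inflammatory mediators (6.22) highest; with library totals alone values move up by 0.863 and the pentose phosphate and colon medians become positive.

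Across the 31 lists, 17 were called by camera with its preset correlation, 9 higher and 8 lower in tumor. With an estimated correlation 1 list was called, and for each of the 17 that p was the highest over all alternatives run. Among the 35 ways of dividing the 8 libraries into 4 and 4, 15 gave 17 or more called lists, the real one included, and the highest of the others gave 22. The 14 others each set 3 libraries of a tissue against 1, so they still hold part of the tissue difference, and the 18 splits with 2 libraries of each tissue on both sides gave 0 to 10 lists. Counts adjusted over the list alone equalled those over all genes tested in every list except smooth muscle, where 4 rather than 5 genes rose.

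The 8 largest rises among abundant genes were in Bpifb5, T, Alb, Bpifb1, Krt6a, Lipf, Wfdc18 and Gkn3. Bpifb5, of a family of secreted lipid-binding proteins, was at 209 ± 53.0 CPM in tumor (SD, n = 4) with 0 counts in small intestine, at least 3800-fold higher against a floor of 3 counts per library. T, the mesoderm transcription factor brachyury, was at least 615-fold higher, the squamous keratin Krt6a at least 438-fold higher and the gastric lipase Lipf at least 371-fold higher on the same floor. Albumin, Alb, held 38641 counts in tumor and 1 in small intestine, a ratio of 25600 (95% exact binomial interval 4590 to 1010000), and without small intestine replicate 1, which held that read, at least 2110-fold. Bpifb1 gave a ratio of 18900 (3400 to 748000), or at least 1660-fold without small intestine replicate 3, and the stomach gene Gkn3 a ratio of 12000 (3310 to 98900). Wfdc18, a secreted protease-inhibitor-type protein, was at 252 ± 109 CPM in tumor and 0.0227 ± 0.00821 CPM in small intestine, a log2 fold change of 13.32 ± 0.64. Bpifb1 and Bpifb5 belong to a family of related genes, and reads shared between copies were not examined.

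The 8 largest falls were in Cyp3a11, Plb1, Cyp3a44, Slc5a4a, Slc5a4b, Enpp7, Lct and G6pc. Cyp3a11, a drug-metabolizing cytochrome, was at 0.102 ± 0.155 CPM in tumor and 518 ± 273 CPM in small intestine, a log2 fold change of -12.31 (-14.27 without tumor replicate 2). Its close relative Cyp3a44 held 4861 counts in small intestine and 3 in tumor, a ratio of 2450 (95% exact binomial interval 836 to 11900), which was 5330 without tumor replicate 1 and 1460 without small intestine replicate 4. The brush border phospholipase Plb1 was at 0.252 ± 0.0584 against 514 ± 396 CPM and the alkaline sphingomyelinase Enpp7 at 0.351 ± 0.201 against 562 ± 399.9 CPM. Without small intestine replicate 3 the log2 fold changes of Plb1 and Enpp7 were -10.29 and -10.06, against -10.97 and -10.65 with all libraries. Slc5a4a and Slc5a4b, adjacent sugar transporter relatives, fell by 10.91 and 10.80, Slc5a4a standing at -11.54 without tumor replicate 1. Paralog pairs such as these, and overlapping or antisense genes, are uncertain, since the strand setting of the counting is not given in the sources used here.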

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

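The search for outlying libraries was planned before the data were examined. In each group of 4, a library was picked out where its gap to the nearest other, over the group's range, exceeded Dixon's 95% critical value, and 21 of 236 groups met this, against 11.8 that chance gives at about 1 in 20. No library total, normalization factor or share of counts was among them, and no library was picked out in more than 5 genes.

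In small intestine, replicate 3 held 331.9 CPM of Lct (the others 56.7 to 91.9), 285.3 CPM of Apoc3 (119 to 147), 33.96 CPM of Slc2a7 (14.4 to 15.6), 0.02099 CPM of Bpifb1 (the others 0) and 0 CPM of Fgf10 (0.0172 to 0.0177). Replicate 1 held 1256 CPM of Defa22 (410.0 to 464), 1.649 CPM of Gfi1b (0.672 to 0.777) and 0.01736 CPM of Alb, a single read (the others 0). Replicate 2 held 0.1591 CPM of Ly6g (0 to 0.0172) and 0.0884 CPM of Mmp8 (the others 0). Replicate 4 held 0.9312 CPM of Adgre1 (1.15 to 1.18).

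In tumor, replicate 4 held less Alb than the others, 52.35 CPM against 138 to 141. It held more of the class II genes H2-Aa (213.8 CPM, the others 115 to 125) and H2-Ab1 (281.6 CPM, 153 to 163) and of the mitotic genes Bub1 (40.78 CPM, 28.8 to 30.7) and Top2a (431.9 CPM, 343 to 351). Replicate 3 held 446.1 CPM of Clca1 (59.8 to 105), 5.265 CPM of Trpm5 (2.01 to 2.42) and 0.4469 CPM of Gfi1b (0.0338 to 0.0495). Replicate 2 held 0.3342 CPM of Cyp3a11 (0.0221 to 0.0279) and 0.8416 CPM of Apoc3 (0.307 to 0.353).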

How the results depend on the processing

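The alternatives were planned before the data were examined, except the one that left out small intestine replicates 1 and 2 together. The total of 12649 called genes ran from 10623 to 13635 over the other settings without a fold minimum, and a minimum of 2-fold left 8645, of which 3887 were lower in tumor. The split by direction moved. Without composition correction, 10564 genes were higher and 2996 lower, and limma on FPKM gave 8297 higher and 2326 lower; 925 and 978 of the genes called with TMM changed direction, and 9615 and 7158 kept theirs. The median of all genes moved by 0.863 and 0.80 on the log2 scale. In the counts only the scaling was changed; the FPKM values differ in test, pseudocount and filter too, and which of these moved their split was not tested. With DESeq2's size factors 12522 of the calls kept their direction and none changed it. Leaving out small intestine replicates 1 and 2 gave 12335 genes and 17 lists. Leaving out each library gave 12049 to 12917 genes. The FPKM count of 10623 was 10610 with a pseudocount of 0.1, 14181 without a filter, and 10198 to 10751 with each library left out. Called lists numbered 17, between 15 and 19 under other scalings, filters and libraries, 1 with an estimated correlation and 28 with fry (fry asks another question, and camera with an estimated correlation differs from the main test in the correlation alone). The direction of the proximal small intestine genes, never called, turned in camera without composition correction (adjusted p = 0.511), with DESeq2 (0.927), on FPKM (0.106), with the replicate number as a block (0.901) and without single libraries (0.54 to 0.98); the cause was not tested. Of 1926 alternative values for 114 named genes, 1919 kept direction and side of the threshold, 5 lost the call (Ndrg1, Gfi1b and Ret), 2 gained it (Apc) and none reversed. Of 589 for the lists, 530 did so, 28 lost the call, 23 gained it and 8 reversed. Leaving out a single library moved 24 of the 114 named genes by over 1.5 times, largely genes near the floor in 1 tissue. Replicate numbers are shared by the groups, and nothing in the labels says whether they pair the samples. Same-numbered libraries correlated at -0.0672, -0.0763, 0.0136 and -0.159, and for each number the highest correlation was with another number. Low correlations between 2 tissues cannot show that the samples were unpaired. The replicate block gave 11893 genes and 17 lists, with 10355 genes from FPKM; the macrophage list was then not called (0.0513) and the T cell list was (0.038). Depth limits genes near the floor of 0.0331 to 0.0630 CPM, and the low-count filter left 23 list members with counts untested, with group means of up to 4.29 CPM.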

Other observations

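Gene groups in the next paragraphs, and the tests of the fructose, stromal and albumin patterns, were chosen after the gene table was seen; the counts of other splits of the libraries were planned. Several transcription factors differed between the tissues. Cdx2 and Cdx1, homeobox factors of the intestine, were at 85.2 ± 18.1 and 47.8 ± 6.56 CPM in tumor, against 426 ± 83.3 and 263 ± 47.0 CPM in small intestine (SD, n = 4 each). Hnf4g, an enterocyte nuclear receptor, was at 10.6 ± 0.790 against 242 ± 31.7 CPM, and its relative Hnf4a at 250 ± 25.9 against 1668 ± 355 CPM. Sox17, an endoderm factor, was at 143 ± 66.0 against 0.0869 ± 0.0971 CPM, Sox21 at 30.6 ± 10.8 against 0.483 ± 0.147 CPM, and Etv5, a factor that responds to growth factor signals, at 305 ± 32.0 against 1.51 ± 0.228 CPM. Each of these passed the edgeR test, at log2 fold changes of -2.32 for Cdx2, -2.46 for Cdx1, -4.51 for Hnf4g, -2.74 for Hnf4a, 10.60 for Sox17, 5.98 for Sox21 and 7.65 for Etv5. Gata6 passed it too, at 63.7 against 90.7 CPM, a log2 fold change of -0.51 that lies within the shift between scalings.

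Transcripts of stomach epithelium appeared in tumor. Of 17 such genes 12 could be tested and 11 rose, with the mucin Muc6 at 143 ± 61.2 against 0.167 ± 0.103 CPM and the protease Ctse at 295 ± 90.7 against 1.41 ± 0.781 CPM. Gkn1 was at 9.13 ± 0.540 CPM in tumor with 0 counts in small intestine, and Muc5ac at 3.96 ± 2.26 CPM in tumor. Haptoglobin, Hp, was at 151 ± 24.7 against 0.529 ± 0.613 CPM.

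Whether other groupings of the libraries would give results as large was counted over the 35 ways of dividing them into 4 and 4. For the 12649 genes called, 1 of 35, the real one, gave as many and the highest other gave 0. The 10623 genes of the FPKM table gave 1 of 35 and a highest other of 0. Every other split held both tissues on each side, so the tissue difference became spread within groups, which leaves little room for calls. These gene counts therefore do not decide whether chance division gives as many. For the 17 called lists, 15 of the 35 gave as many, the highest other being 22. The 14 others each set 3 libraries of a tissue against 1, which keeps part of the tissue difference, and the 18 splits with 2 libraries of each tissue on both sides gave 0 to 10 lists, so the share over all 35 does not decide whether chance gives 17. The preset correlation of 0.01 lies below the correlations estimated for most lists, for example 0.43 for fructose and 0.75 for cell cycle genes.

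Explanations examined for the fall of the 9 fructose genes in tumor were epithelium diluted by other cells, the scaling, and fewer mature enterocytes. Others, among them the gut region sampled, were not tested. Dilution would lower general epithelial genes alike, but of 14 such genes 3 rose and 9 fell (median -0.85), and the lowest had a log2 fold change of -2.425, above the smallest fall among the fructose genes (-3.13). The scaling moves all genes by up to 0.863, and under the 3 other count scalings the least changed fructose gene stood at -2.279. Fewer mature enterocytes and lower expression within them cannot be told apart: the fructose median lay 0.3609 above the enterocyte median of -6.43, which either would allow. As a hypothesis, loss of the fructose genes may be part of the lower enterocyte program.

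Most fibroblast and endothelial genes were higher in tumor, and most T cell genes lower, while 4 of 9 B and plasma cell genes did not pass the test and smooth muscle genes changed less. A smaller share of every non-epithelial cell type, T cells included, in the small intestine libraries would raise all their markers in tumor. The T cell list instead had a median of -2.288, with 11 of 12 members lower. That value does not bear on a loss of stroma that spares T cells. For the fibroblast genes (median 4.495) and endothelial genes, loss from the small intestine samples during preparation and a gain in tumor cannot be told apart. Preparation and tissue go together, and the labels do not describe the dissection. In small intestine Col1a1 was at 3.99 CPM and Cdh5 at 1.65 CPM, beside the epithelial Epcam at 3661 CPM and the muscle marker Mylk at 227 CPM. The same limit holds for the macrophage, neutrophil and inflammatory genes that rose. B cell and adipocyte transcripts of small intestine replicates 1 and 2 do not account for the count of called genes, which was 12335 without both. A difference in lymphoid and stromal makeup between the tissues stays open and was not tested on cells.

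Albumin and gastric transcripts were found in each tumor library. Liver tissue in the samples would bring its other abundant transcripts, yet 15 of them other than Alb had a median of 0.219 CPM in tumor, 12 of all 16 lying under 1 CPM, with Fgb at 0.00309 and Apoa2 at 0.807 CPM while Alb was at 118 CPM. Hp at 151, Trf at 5.50 and Ttr at 3.02 CPM were exceptions, and 6 of the 9 members tested rose. These values argue against liver as the source of Alb. Stomach tissue stays open. The 17 gastric genes had a median of 1.55 CPM in tumor over a wide range, and 7 were under 1 CPM, while 11 of the 12 tested rose. Ctse, Muc6, Gkn3 and Lipf were at 295, 143, 108 and 20.4 CPM, and Gkn2, Tff2 and Atp4b at 0.244, 0.189 and 0 CPM. The gastric median includes Gkn3 and Lipf, which are among the largest rises, whereas Alb was left out of the liver median. Expression by cells of the tumor was not tested.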
